A study of Drosophila melanogaster with 4 samples.

How the data were processed

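The study compared heads of Oregon-R wild-type Drosophila melanogaster males, unmated and 10 to 11 days old at the start, that were kept for 3 days on normal food (NF) or on food with vigabatrin (VGB) at 24 mg per ml. Vigabatrin is an antiepileptic drug that blocks GABA transaminase, the enzyme that breaks down the transmitter GABA. Each vial held 30 flies. RNA from pooled heads of 4 parallel sets, each with a treated and an untreated pool, was hybridised to 4 spotted cDNA arrays, 1 array per set. VGB carried the dye Cy5 on replicates 1 and 2 and Cy3 on replicates 3 and 4.

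Per the labels and the design text, the authors scanned the slides, quantified them with GenePix Pro 6.0 and normalized the dye ratio with Acuity 4.0, leaving out of the normalization spots of low raw intensity (100 units) or low signal over background. They kept spots with under 3% saturated pixels, no bad flag, a regression R2 of at least 0.6 and a signal-to-noise ratio of at least 3. They used one-class SAM 2.21 with 100 permutations on spots present in at least 3 arrays. The deposited values are log ratios of the 2 dyes, here taken as log2, since the base is not given in the sources used here. The values run below 0 on every array, which a linear ratio of positive intensities would not. Scale, centring and the direction on the dye-swapped arrays are not stated: the column medians were 1.03, 1.04, 0.52 and 0.45 for replicates 1 to 4, so the values were not centred on 0.

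The array holds 27648 spots, printed as 13824 adjacent duplicate pairs, and the 2 spots of each of the 7609 annotated pairs carried the same gene and accession. The mean of a pair is called a probe below. Gene names came from GEO's platform annotation, which is old, updated by gene identifier through a table of Release 6 genes. Of the probes, 7558 had 1 gene, 51 had several and 6215 had none listed there. A current symbol was found for 7447 of the 7558, and the other 111 kept the annotation's symbol. No gene was named from a probe with several, and no genome build is named, so no position is given.

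The direction of the ratios could not be settled by the rules fixed before the data were examined (number format, mean at a fixed value, control spots, clearly negative correlation between arrays of opposite dye order). As fixed for that case, the main coding took the values as Cy5 over Cy3 and turned the sign of replicates 3 and 4. The other coding takes all 4 as VGB over NF. Every direction below depends on this choice.

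The test was limma 3.58.1 (lmFit and eBayes, R 4.3.3) with an intercept only, two-sided, with Benjamini-Hochberg adjustment at 0.05 over the 1114 probes measured on at least 3 arrays. The design fixed before the data were examined took the values with no further centring. Because each array sits off 0 and 2 arrays are turned, that fit puts a spread of about 1 between arrays on every probe. Values of genes are therefore given relative to each array's median, a setting listed before the data were examined. The choice to lead with it was made after seeing the medians, and both counts are given. The median over tested probes moved from 0.20 as deposited to -0.04 after centring. Alternatives applied to centred values join 2 choices and were chosen after seeing the data, as were single spots, centring of each printed block of 576 spots, and the probe-level variance prior at gene level. That last one was added because limma's prior had 567 degrees of freedom at gene level against 11.8 at probe level, so gene-level p-values rest almost on a common variance. FLASH, a gene with 2 probes, was named after its values were seen. It was called at gene level at -0.71 ± 1.26 (SD, n = 4) with 2 arrays on each side of 0.

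Genes were named by a rule fixed before the data were examined: up to 12 per direction past the threshold with 1 sign on every array measured. The list was filled up to 12 with the smallest p-values having 1 sign on all 4 arrays, said not to pass. Every measured gene of the GABA list was added, and up to 4 genes of a list that passed its set test or held a gene past the threshold over the list alone. The adjustment over a list alone was made within each list, with no correction over the 27 lists. Up to 2 genes of other described lists followed. The rule was applied to the centred fit; on the values as deposited it named Atf6 alone, at 0.44 ± 0.37 (SD, n = 4) with a limma adjusted p of 0.997. Gene lists (27, of which 5 member names matched no gene) were fixed in advance. Lists with at least 5 genes on all 4 arrays were tested with camera at a preset correlation of 0.01, with fry and an estimated correlation beside it.

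On data simulated with the observed missing values and spread, with 200 of 1114 probes changed, limma on centred values recovered 67.8% of 1.5-fold and 99.3% of 2-fold changes, with 5.8 and 9.0 false calls on average. On values carrying the arrays' offsets it recovered 0% of both and 74.8% of 3-fold changes. A one-class SAM written out here, with all 16 sign assignments, made calls equal to 16.0% and 45.2% of the changed number at 1.5-fold and 2-fold, and 75.0% and 104.1% when run on the probes measured on all 4 arrays alone. The simulation changed as many probes up as down and drew the arrays independently, with no dye term. Fewer changed probes would make the adjusted threshold stricter, so these shares can overstate recovery where few probes change. Precision is limited by the number of arrays.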

Results

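Gene expression in heads of male flies given vigabatrin (VGB) was measured against flies on normal food (NF) on 4 two-colour arrays, each a separate pair of pools. Values passing the authors' filters covered 5631, 2559, 3032 and 6460 of the 27648 spots on replicates 1 to 4. For 63.6% of the spots no array had a value. After averaging duplicate spots, 1114 probes had a value on at least 3 arrays and 591 on all 4. These included 585 probes with a single gene name.

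**Figure D1:**
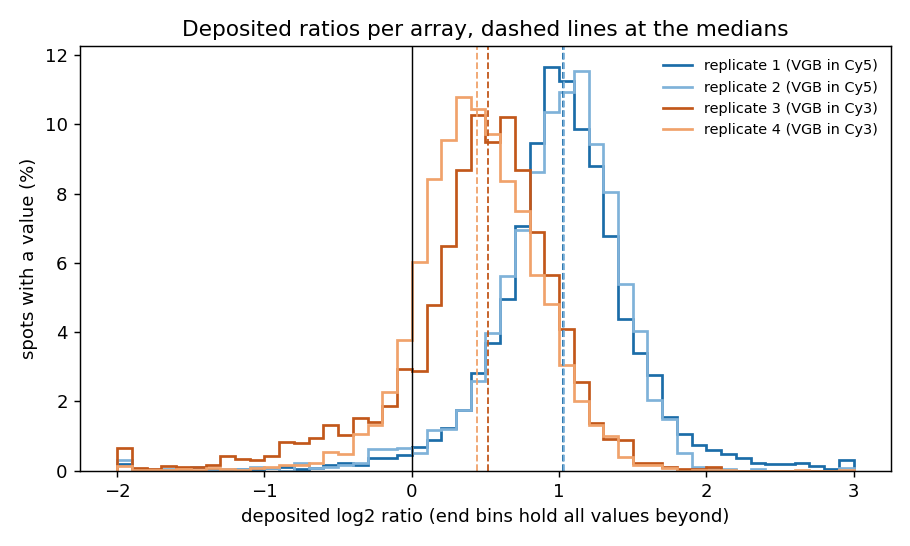
The horizontal axis is the deposited log2 ratio of the 2 dyes, the vertical axis the percentage of spots with a value, in bins of 0.1, with 1 line per array. Dashed lines mark the medians, 1.03 and 1.04 for replicates 1 and 2 and 0.52 and 0.45 for replicates 3 and 4, all above 0.

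The first comparison asked which genes differed between heads of treated and untreated flies. The sign of the values on replicates 3 and 4 is not settled, so each direction holds for the main coding only. Relative to the median of each array, CG16926 fell with VGB by 0.94 on the log2 scale (SD 0.18, n = 4, limma adjusted p = 0.0094), to 52.2% of the NF level, and was lower on 4 of 4 arrays. CG2233 fell by 0.88 (SD 0.27, n = 4, limma adjusted p = 0.017) and was lower on 4 of 4. CG6985 rose by 1.03 ± 0.51 (SD, n = 3, limma adjusted p = 0.039) and was higher on 3 of 3 arrays. Its 2 duplicate spots differed, with means of 0.63 ± 0.28 and 1.44 ± 0.95 (SD, n = 3 each; limma adjusted p = 0.17 and 0.012). CG6985 did not pass with block centring (limma adjusted p = 0.17), quantile normalization (0.12) or at least 2 arrays (0.57), nor without replicate 1, 3 or 4 (0.13, 0.19 and 0.30). CG16926 and CG2233 did not pass with quantile normalization (0.12 for both), at least 2 arrays (0.20 and 0.32) or without replicate 4 (0.29 and 0.31), and CG2233 not with block centring (0.056). With the other coding the same probes stood at 0.05, 0.15 and -0.44, and none passed.

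In all, limma called 1 probe higher and 3 lower among 1114, the third lower probe being unnamed here (-0.96 ± 0.22, SD, n = 3, limma adjusted p = 0.023; outside the naming rule, as it has no gene name). At an unadjusted p under 0.05, 13 probes were higher and 81 lower. Each array's median was taken over all probes with a value on it, not over the 1114 tested. Of the tested probes, 61.0% then lay below 0, with a median of -0.04. How much of the excess of lower probes comes from this was not tested. On the values as deposited, the fit fixed in advance, limma called 0 higher and 0 lower, with 0 probes at an unadjusted p under 0.05 and 0 calls by one-class SAM. One-class SAM on centred values called 0 higher and 3 lower. Without replicate 4, no probe passed on centred values, and without replicate 2 there were 6 higher and 17 lower.

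Further genes with 1 sign on all 4 arrays had the next smallest p-values on the lower side. The 2 probes of apolpp, the precursor of the main lipid carrier of the haemolymph, had mean log2 ratios of -0.64 ± 0.39 and -0.61 ± 0.36 (SD, n = 4; limma adjusted p = 0.17 for both). Mdh1, a cytosolic malate dehydrogenase, stood at -0.46 ± 0.13, AcCoAS, an acetyl-CoA synthetase, at -0.45 ± 0.17, and Papss, which makes the sulfate donor PAPS, at -0.47 ± 0.28 (SD, n = 4; limma adjusted p = 0.25 for each). The mitochondrial ribosomal protein gene mRpS34 had -0.88 ± 0.64 (SD, n = 4; limma adjusted p = 0.090). Its values were -0.31 and -0.35 on replicates 1 and 2 against -1.31 and -1.54 on replicates 3 and 4. CG44014, CG4716, CG11400 and Jhbp14 had means of -0.61 ± 0.41, -0.60 ± 0.37, -0.53 ± 0.33 and -0.52 ± 0.38 (SD, n = 4). Their limma adjusted p were 0.17, 0.17, 0.23 and 0.25. They too lay lower on replicates 3 and 4 (means of -0.96, -0.90, -0.81 and -0.81) than on replicates 1 and 2 (-0.27, -0.30, -0.25 and -0.23). None of these probes passed in this fit. At gene level, where limma's variance prior is close to a common variance, apolpp, mRpS34, CG44014, CG4716, CG11400 and Jhbp14 passed (limma adjusted p = 0.0048, 4.3e-06, 0.0062, 0.0076, 0.030 and 0.036). With the probe-level variance prior none of the 6 passed (limma adjusted p from 0.055 to 0.21), nor without replicate 4 (0.50 to 0.80).

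On the higher side the genes filling the list had small ratios and none passed. At gene level 2 genes were higher and 13 lower (1 and 2 with the probe-level variance prior). Pxn, named after its values were seen, was the other higher one beside CG6985, at 0.86 ± 0.44 (SD, n = 3, higher on 3 of 3 arrays; limma adjusted p = 0.00027, 0.055 with the probe-level variance prior, 0.21 without replicate 3 and 0.57 without replicate 4), and stood at -0.60 with the other coding. Pxn is a gene with 2 probes. CG6424 had 0.33 ± 0.30 and CG8321 0.25 ± 0.34 (SD, n = 4), the latter 0.08 without replicate 3. Ric, a Ras-like GTPase gene, had 0.20 ± 0.09 and Nhe3, a sodium-proton exchanger gene, 0.17 ± 0.12 (SD, n = 4). The means of ens, Rnf146, eIF4G1, Pect, CG14989, RalGPS and CG6329 were 0.14, 0.13, 0.13, 0.11, 0.11, 0.10 and 0.10. Leaving out 1 array lowered ens to 0.07 and eIF4G1 to 0.05 (replicate 1), CG14989 to 0.05 (replicate 2) and CG6329 to 0.06 (replicate 4). Limma adjusted p for these 11 genes ran from 0.575 to 0.989. Of the 591 probes on all 4 arrays, 68 were lower and 21 higher on every array, 15.1% together. Independent arrays would give 12.5%, and 15.8% is given by chance when the agreement within each dye order is kept. With the other coding 22 were lower and 108 higher on every array, 22.0% together, against 18.9% by that chance. At an unadjusted p under 0.05 limma then had 131 probes higher and 25 lower, the reverse of the main coding's balance, and one-class SAM called 0 higher and 2 lower. At gene level the other coding gave 4 higher and 1 lower, 0 of them shared with the main coding's calls. The main coding's gene-level counts were 0 and 0 as deposited or with at least 2 arrays, 0 and 4 with block centring, and 1 and 1 without replicate 4.

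**Figure D2:**
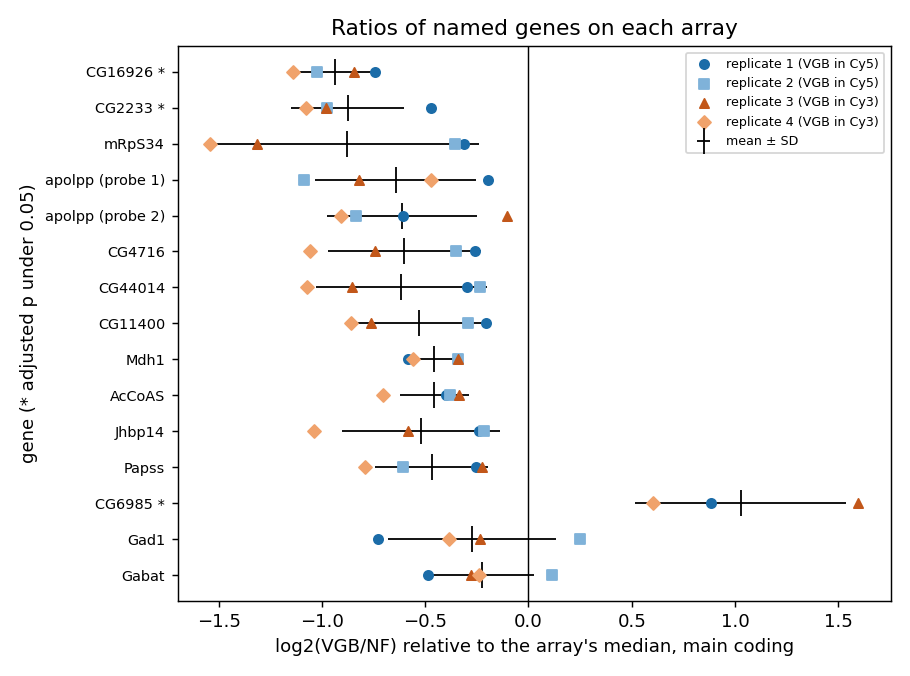
Each row is a probe of a named gene, the horizontal axis its log2 ratio of VGB over NF relative to the median of the array in the main coding, points the 4 arrays, and black lines the mean ± SD. The lower probes include those that did not pass and filled the list for lying below 0 on all 4 arrays. On the higher side only CG6985, which passed, is drawn, and the genes that filled that list are left out. CG16926 and CG2233 lie below 0 on all 4 arrays, CG6985 above 0 on the 3 arrays that measured it, and Gad1 and Gabat on both sides of 0.

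The genes nearest to the drug's action were measured sparsely. Of 12 genes of GABA synthesis, transport, reception and breakdown, 6 were on the array and 2 had values on at least 3 arrays. Gad1, the glutamate decarboxylase that makes GABA, had -0.27 ± 0.41 (SD, n = 4; limma adjusted p = 0.84). Gabat, the GABA transaminase that vigabatrin blocks, had -0.22 ± 0.25 (SD, n = 4; limma adjusted p = 0.89). Both were lower on 3 of 4 arrays and neither passed, also when adjusted over the list alone (smallest adjusted p = 0.15). As deposited they stood at 0.01 and 0.06, and with the other coding at 0.04 and 0.04. Without replicate 1 the means were -0.12 and -0.14 and without replicate 2 -0.45 and -0.34, and Gad1 stood at -0.12 with block centring.

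Lists of related genes were then compared with all other genes. No list differed by camera as deposited (smallest adjusted p = 0.996) or after centring (smallest adjusted p = 0.94), nor with an estimated correlation (smallest adjusted p = 0.97 after centring). Only 4 lists had 5 or more genes on all 4 arrays. Their mean log2 ratios were -0.06 for phototransduction (6 genes), -0.11 for detoxification (5), -0.08 for oxidative phosphorylation (10) and -0.06 for glycolysis and the TCA cycle (7). These means were, with the other coding, 0.13, 0.00, 0.16 and 0.01. The median of the last list over its genes on all 4 arrays was 0.02, opposite in sign to its mean.

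Within the glycolysis and TCA list, 9 genes had values on at least 3 arrays, 5 below and 4 above 0, against 2 below as deposited. Enolase (Eno) had -0.68 ± 0.48 (SD, n = 3) and passed limma at gene level over all genes (adjusted p = 0.010) and, with Mdh1 (-0.46 ± 0.13, SD, n = 4), when adjusted over the list alone (adjusted p = 0.0017 and 0.015). Over all genes Eno no longer passed with the probe-level variance prior (limma adjusted p = 0.19), quantile normalization (0.099), block centring (0.16) or at least 2 arrays (0.58), and without replicate 4 (0.74) or replicate 3 (0.92, with a mean of -0.43). Its mean was 0.54 with the other coding (limma adjusted p = 0.24). Adjustment over a list alone does not correct for the number of lists, so some such passes can arise by chance, here and below. Over the list alone neither Eno nor Mdh1 passed without replicate 4 (limma adjusted p = 0.083 for both) or without replicate 3 (0.27 and 0.072), and Mdh1 not with block centring (0.15) or without replicate 1 (0.17). PCB and Gapdh1 stood at -0.15 and -0.11 and did not pass. PCB ran from -0.25 on replicate 1 to -0.07 on replicate 3, and Gapdh1 from -0.33 on replicate 4 to 0.11 on replicate 2.

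Of the 11 nutrient and lipid genes with a value on any array, 4 had values on at least 3, and these 4 lay below 0 (3 of them as deposited). Of the other 7, with values on 1 or 2 arrays, 4 lay below and 3 above 0. FASN1, a fatty acid synthase, had -0.48 ± 0.38 and Desat1, a fatty acid desaturase, -0.45 ± 0.24 (SD, n = 4). Neither passed over all genes (limma adjusted p = 0.065 and 0.098). Both passed when adjusted over the list alone (0.0078 and 0.0083), with no correction for the number of lists. Over the list alone neither passed with block centring (limma adjusted p = 0.087 and 0.061), without replicate 4 (0.089 for both) or without replicate 3 (0.14 and 0.071), and Desat1 not without replicate 1 (0.062). Ilp2 and Hnf4 stood at -0.18 and -0.11, and at 0.08 and -0.03 without replicate 4. Of 7 fat body markers with a value on any array, only apolpp had values on at least 3, with a gene-level mean of -0.63 ± 0.25 (SD, n = 4; limma adjusted p = 0.0048 over all genes, 0.064 with the probe-level variance prior, 0.083 without replicate 2 and 0.50 without replicate 4). The other 6 had values on 1 or 2 arrays, 3 below and 3 above 0. With the other coding apolpp, FASN1 and Desat1 stood at -0.05, 0.31 and 0.14.

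Of all 565 genes tested, 59.3% lay below 0 after centring and 21.2% as deposited, so counts of genes below 0 in a list depend on the scaling. Among odorant-binding proteins, 4 of 5 genes lay below 0, against 2 as deposited. Obp99c had -0.56 ± 0.52 (SD, n = 3) and Obp56d -0.37 ± 0.33 (SD, n = 4), past the threshold when adjusted over the list alone (limma adjusted p = 0.0097 and 0.043) but not over all genes, and not over the list with the probe-level variance prior or block centring (limma adjusted p = 0.069 and 0.090, the same for both). Obp56d was a mean of 2 probes, -0.46 ± 0.33 with no value on replicate 1 and -0.32 ± 0.43 with none on replicate 3. Each had n = 3 (SD), with limma adjusted p of 0.43 and 0.84. Without replicate 4 Obp99c stood at -0.31 and Obp56d at -0.23, and neither passed over the list alone (limma adjusted p = 0.30 for both), nor did Obp56d without replicate 1 (0.073) or 3 (0.16). Obp57c stood at -0.16 (-0.33 without replicate 1, -0.04 without replicate 4) as a mean of 2 probes that disagreed, -0.56 ± 0.29 (SD, n = 3; lower on 3 of 3 arrays, limma adjusted p = 0.25) and 0.01 ± 0.40 (SD, n = 4). Obp56g stood at 0.38 as a mean of 2 probes that disagreed, 0.92 ± 0.64 and -0.16 ± 0.33 (SD, n = 3 each). All 7 ribosomal protein genes on at least 3 arrays lay below 0, against 3 as deposited, led by RpL39 (-0.38 ± 0.15) and RpS7 (-0.31 ± 0.06; SD, n = 3 each), and none passed. The phototransduction list held 5 genes below and 3 above 0, against 1 below as deposited, with Pdh at -0.21 and trpl at -0.18. The oxidative phosphorylation list held 11 below and 2 above, against 2 below as deposited, with ND-SGDH at -0.23 and ATPsynG at -0.23. The detoxification list held 5 below and 2 above, against 2 below as deposited, with the cytochromes P450 Cyp28d1 at -0.37 and Cyp4e2 at -0.38. None of these passed over all genes or over its list alone. Without replicate 4 the means of Pdh, trpl, Cyp4e2, ND-SGDH and ATPsynG were -0.03, -0.08, -0.19, -0.39 and -0.12. ND-SGDH stood at -0.56, -0.22 and 0.09 on replicates 2, 3 and 4, so its mean rests mostly on replicate 2.

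Neural lists had few measured genes and no gene past the threshold. The glutamate list had 2 genes, monoamine 3, neuropeptide 2, synaptic vesicle 4, voltage-gated channels 2, seizure mutants 1, and acetylcholine and circadian clock 0. Markers of other tissues were as sparse, with 1 neuronal, 1 glial, 3 muscle, 2 digestive and 1 male reproductive gene tested and none called. The median log2 ratios were -0.27, -0.04, 0.00, -0.21 and -0.23 for these. The heat shock list had 2 genes, immune 1, proteasome 2, and chromatin and cuticle 0, again with no call.

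A dye effect was estimated with treatment and dye in one limma model over the 591 probes on all 4 arrays. As deposited, 590 probes had a dye term past the threshold, 589 toward Cy5, which follows from the medians above 0. After centring, 41 probes did, 38 of them toward Cy5. They included RpL27 with a dye term of 0.58, Npc2a with 0.56 and mRpS34 with 0.55 (limma adjusted p = 0.014 for each), of which RpL27 and Npc2a were chosen after their values were seen. In this model 1 probe was higher and 26 were lower with VGB, CG16926, CG2233, mRpS34, FASN1, Mdh1, Desat1 and both apolpp probes among the lower. CG44014, CG4716, CG11400, Jhbp14, AcCoAS and Papss, which did not pass without the dye term, were also among the lower (limma adjusted p from 0.0050 to 0.037). As deposited the same model gave 161 higher and 8 lower, the opposite balance. This follows from the offsets of the arrays, which with 2 arrays turned raise every treatment term by the same amount (CG16926 from -0.94 to -0.66). With the other coding the treatment and dye terms change places.

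Across spots, which are not independent replicates, the arrays of 1 dye order correlated with Pearson r = 0.44 for replicates 3 and 4 (Spearman 0.40) and 0.19 for replicates 1 and 2 (Spearman 0.17). Arrays of opposite dye order had r from -0.01 to 0.15 (Spearman 0.01 to 0.16) on the values as deposited. The main coding turns replicates 3 and 4, so in it these correlations change sign. They were then near 0 or weakly negative, so arrays of opposite dye order did not agree across spots in the main coding.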

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

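The tests of dye order, of noise outside the probes on all 4 arrays, and of the sign assignments were chosen after the result was seen. Replicate 1 had 241 duplicate pairs whose spots differed by more than 1 on the log2 scale, against 27, 26 and 55 on the other arrays, and stood apart on that count. The arrays held unlike numbers of pairs with both values, and as shares of these the counts were 8.6%, 2.1%, 1.7% and 1.7% on replicates 1 to 4. CG2233 stood apart on replicate 1 at -0.47, CG8321 on replicate 3 at 0.75 and eIF4G1 on replicate 1 at 0.34. Of 31 results looked at in this way, chance alone would mark about 1 in 20.

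Duplicate spots on replicate 1 correlated with r = 0.23, against 0.64, 0.82 and 0.65 on the other arrays. Neighbouring spots of different probes correlated there with r = 0.23 as well, and with 0.15 after centring each printed block, where duplicates had r = 0.17. This decides nothing on a trend across the slide, since a trend shifts adjacent duplicates alike and removing it can only lower their r. Over the 591 probes on all 4 arrays r rose to 0.52, still below the lowest of the others, 0.71. That bound was a poor one for dim spots, because r also falls where probes differ little: over those probes the SD of duplicate differences on replicate 1 was 0.25, no higher than the 0.25 of replicate 2. The median absolute difference was the highest of the 4 arrays there, 0.15 against 0.14, 0.12 and 0.10, so dim spots and noise outside these probes both stay open, and intensities were not used here. No biological explanation was tested.

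The values may have been deposited in the same dye order on all 4 arrays, or with replicates 3 and 4 already turned to VGB over NF. Among discordant duplicate pairs, the outlying spot was the low one in 77.8% of pairs on replicates 3 and 4 pooled (95% exact binomial interval 67.2 to 86.3). These 2 arrays differed, with 26 of 26 pairs on replicate 3 (interval 86.8 to 100%) and 37 of 55 on replicate 4 (53.3 to 79.3%). The pooled interval therefore describes neither array. The outlying spot was also the low one in 85.2% on replicate 2, but in 118 of 241 on replicate 1 (interval 42.5 to 55.5%), so a common side for replicates 1 and 2 is missing and the 2 codings cannot be told apart. No biological explanation was tested.

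The 4 calls on centred values were set against the other sign assignments of the 4 arrays. Of the 8 distinct assignments, 1, that of the main coding, gave as many, and the highest of the others, the other coding among them, gave 0. As deposited, the main coding gave 0, so all 8 gave as many, and the highest of the others gave 1068, the other coding, with no array turned, which follows the offset shared by all arrays. With 8 assignments a share under 0.05 cannot be reached.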

How the results depend on the processing

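Alternatives applied to centred values, single spots, block centring and the probe-level variance prior were chosen after seeing the data. Counts below are probes higher and lower with VGB. On the values as deposited (0 and 0), centring gave 1 and 3, centring with scaling to one spread 2 and 5, quantile normalization 1 and 0, a dye term 161 and 8, the other coding 1067 and 1 (the offset shared by all arrays), and block centring 0 and 1. The remaining settings gave 0 and 0 as deposited, but that fit recovered no simulated 2-fold change, so this says nothing about stability. On centred values (1 and 3), scaling gave 2 and 5, quantile normalization 0 and 0, at least 2 arrays 0 and 0, only probes on all 4 arrays 0 higher, the other coding 0 and 0, a dye term 26 lower, gene level 2 and 13 (1 and 2 with the probe-level variance prior), single spots 2 and 7, block centring 0 and 1, SAM 0 higher, and adjusted p under 0.1 gave 5 lower. Leaving out 1 array gave 0 to 6 higher and 0 to 17 lower: without replicate 1, 0 and 2, without replicate 2, 6 and 17, without replicate 3, 0 and 5, and without replicate 4, 0 and 0. Gene-level counts were 4 and 1 with the other coding, and 0 and 0 as deposited or with at least 2 arrays. Without replicates 1, 2, 3 and 4 in turn they were 2 and 9, 3 and 12, 0 and 6, and 1 and 1. The cause was not tested, except that the other coding turns 2 arrays by construction. In the fit with a dye term as deposited, the offsets of the arrays also raise every treatment term.

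The 590 dye terms as deposited became 41 after centring, and leaving out 1 array gave 585 to 588. No list passed under any alternative. Over the 1182 spots on all 4 arrays, as deposited, r moved from 0.13 to 0.084 for replicates 2 and 3. It moved from 0.15 to 0.080 for 2 and 4, and from 0.44 to 0.52 for 3 and 4. For 1 and 2 it went from 0.19 to 0.17, for 1 and 3 from 0.05 to 0.08, and for 1 and 4 from -0.01 to -0.02. Spots are not independent, so no interval is set on these moves.

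Over the lists alone, Eno, Mdh1, FASN1, Desat1, Obp99c and Obp56d passed neither with at least 2 arrays (adjusted p from 0.062 to 0.088) nor as deposited or with the other coding. At gene level, Eno's adjusted p ran from 0.0057 to 0.996 over its alternatives. CG16926 passed in each alternative on centred values except quantile normalization, at least 2 arrays, the other coding and without replicate 4 (limma adjusted p from 1.5e-06 to 0.96 over its alternatives on centred values). CG2233 also missed with block centring (adjusted p = 0.056), and CG6985 with block centring (0.17), on the first of its 2 spots (0.17) and without replicates 1, 3 or 4.

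With the other coding the sign turned for CG16926 (0.055), CG2233 (0.15), mRpS34 (0.55), 1 of the 2 apolpp probes (0.0026), CG4716 (0.30), CG44014 (0.35), CG11400 (0.28), AcCoAS (0.064), Jhbp14 (0.29), Papss (0.039), CG6985 (-0.44), CG6424 (-0.031), CG8321 (-0.16), Ric (-0.027), Rnf146 (-0.054), CG6329 (-0.034), Gad1 (0.035) and Gabat (0.038). At gene level it turned for Eno (0.54), Gapdh1 (0.12), Obp99c (0.15), Obp56d (0.25), Obp56g (-0.28), Obp57c (0.16), FASN1 (0.31), Desat1 (0.14), Ilp2 (0.21), Hnf4 (0.21), Pdh (0.19), trpl (0.39), Cyp4e2 (0.13), ATPsynG (0.28), RpL39 (0.24) and RpS7 (0.13). The list means turned to 0.13 for phototransduction, 0.0024 for detoxification, 0.16 for oxidative phosphorylation and 0.0064 for glycolysis and the TCA cycle. As deposited, the sign turned for Gad1 (0.0056), Gabat (0.057), PCB (0.37), Gapdh1 (0.16), Obp57c (0.12), Hnf4 (0.17), Pdh (0.068), trpl (0.10) and Cyp4e2 (0.16), and for the list means (0.22, 0.17, 0.20 and 0.22 in the order above), by the offsets of the arrays. Leaving out 1 array moved Ilp2 from -0.34 to 0.079, phototransduction from -0.15 to 0.042, oxidative phosphorylation from -0.17 to 0.030 and glycolysis and the TCA cycle from -0.15 to 0.029, each highest, and above 0, without replicate 4. The detoxification mean ran from -0.20 without replicate 3 to -0.013 without replicate 4. Signal over background was not used here beyond the authors' filters, which left few spots measured on all 4 arrays.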

Other observations

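The tests of dye bias, of the fat body share and of neighbouring spots were chosen after the result was seen, and so was the joining of the 2 lists fixed in advance, fat body markers with nutrient and lipid genes. The 5 genes of the joined list with values on at least 3 arrays were apolpp, FASN1, Desat1, Ilp2 and Hnf4. Their means lay below 0 in the main coding after centring, with a median of -0.45, where 59.3% of all 565 genes lay below 0. Ilp2 stood above 0 on replicates 1 and 3 (0.03 and 0.12) and at -0.71 on replicate 4. Hnf4 stood above 0 on replicates 1 and 2 (0.06 and 0.14) and at -0.28 and -0.35 on replicates 3 and 4. As deposited Hnf4 stood at 0.17 and the other 4 below 0, where 21.2% of all genes did. Of the 13 others, with values on 1 or 2 arrays, 7 lay below and 6 above 0. The median of the 5 was 0.21 with the other coding. The lists were joined after these genes were seen to lie low. The joined list was tested against other genes (camera and 10000 random lists), but such a test is circular on these data and is not used.

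A hypothesis is that VGB-fed flies had less of the apolpp, FASN1 and Desat1 transcripts in the head. These lay below 0 on all 4 arrays, and Ilp2 and Hnf4 did not. The medians below are over all 5 genes. Position on the slide cannot be told apart: after centring each printed block the median was -0.33, but neighbouring spots of different probes still correlated with r from 0.13 to 0.40 over the 4 arrays, and the genes were chosen for lying low. Dye bias cannot be told apart from treatment: the median was -0.17 on replicates 1 and 2 and -0.58 on replicates 3 and 4, both below 0, but with the other coding these numbers are the dye term. A smaller share of fat body in the VGB pools cannot be told apart either, as only 1 fat body marker had values on at least 3 arrays. A response to the drug or to eating less of the treated food stays open and untested.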
